A study of Homo sapiens with 51 samples.

How the data were processed

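The series holds 51 total RNA libraries, made with a kit that removes ribosomal RNA, from rectal pinch biopsies of patients with ulcerative colitis treated with tofacitinib. 27 are from week 0 and 24 from week 24. Per the labels' protocols the biopsies were stored frozen, and RNA was extracted from the whole biopsy, so each value is a mean over all its cells. Per the file headers the deposited table holds normalized counts of 28277 genes by gene symbol, and per the submitters' processing notes DESeq2 and the genome build hg38 were used. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes and near-identical gene copies are uncertain.

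The deposited signal is the gene counts that the authors divided by 1 size factor per library. In every column the values were whole multiples of 1 step, and 100% of 1442127 values came back as whole reads within 1e-06 reads. In 2 columns the step was within 1% of 1, where the size of the step alone could not be told from rounding, and these values carried the same full precision. The recovered reads gave the depth, 1.44 to 36.6 M reads per library with a median of 9.27 M. 7 libraries (3 at week 0, 4 at week 24) had under 5 M. Depth limits low genes most. Reads are not independent molecules, so depth speaks of counting error only.

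Columns were matched to the labels by name. A pair of week 24 columns shared a name, so 2 labelled week 24 samples have no column of their own. Both columns were used as week 24 with no patient, which leaves 11 of the 13 labelled pairs. Of 627 pairs of libraries of the same week, none was a copy of another. The squared differences in the median gene were at least 4.17 times those of sampling noise, with a median of 26.7 times. Libraries of different weeks were not compared. The comparison does not show whether 2 libraries came from 1 patient. Of the week 24 biopsies without a pair used, 2 had close list scores, defined below (interferon-gamma 0.59 and 0.51, MHC class II 1.45 and 1.39). Whether they share a patient was not tested. The pairing comes from the patient numbers in the labels. Deviations from the week means correlated within pairs with a median r of 0.121 (−0.0572 to 0.696, over 0.1 in 7 of 11), against a median of −0.0469 between patients. Of the 11 paired week 0 biopsies, 5 correlated best with their own week 24 biopsy. The first principal component held 22.3% of the variance and followed the surface colonocyte score (r = 0.810), and of the first 6 components the third (9.56% of the variance, unadjusted permutation p = 0.0179) and the fifth (4.22%, p = 0.0476) had an unadjusted p under 0.05 for the week. No batch is given in the labels.

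Genes with a mean of at least 10 (15458) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, eBayes with trend and robust, two-sided, all 51 biopsies, no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. A fold change is on the log2(value + 1) scale, which understates that of low genes. On simulated libraries of the same numbers and depths, with 15333 genes tested, this test called 72 of 100 genes changed 2-fold and 86 of 100 changed 4-fold, 12 of its 170 calls were false, and it called 0 with no gene changed. The simulated genes were independent of each other, without pairs, with capped dispersion and with changed genes picked at random. These shares therefore do not carry over to the biopsies, where genes of a list were correlated.

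34 lists of genes, for pathways and cell types of the rectum and of its neighbouring tissues, were fixed in advance. 33 were tested, and that of mitochondrial transcripts had 0 members in the table. Others were tested only in part, such as plasma cells (19 members written, 11 in the table and 10 tested), squamous epithelium (5 of 16 tested) and red blood cells (4 of 8). Lists share some genes, such as TREM1, CIITA, OSM and CA1, the last of which is on the surface colonocyte and the red blood cell list. camera was used with a preset correlation of 0.01, and again with an estimated correlation and with fry. Scores are the mean over a list's genes of log2(value + 1) minus the gene's mean, compared by permutation tests with 100000 resamples, or within patients by exact sign flips (2048, smallest possible p 0.000977). Correlations were given as Pearson r and Spearman rho with permutation p. All tests are two-sided.

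The text names the 10 genes with the smallest p in each direction with a mean of at least 50 (since none passed), up to 4 genes with the smallest p per list, JAK-STAT components, and OSM, IL13RA2, TREM1, IL11, IFNG, IFNGR1 and IFNGR2. Clone names, pseudogenes, antisense genes, sex-linked marker genes and variable segments of immunoglobulins and T cell receptors were left out of the first part (1071 of the tested genes, 18 of them with a mean of at least 50 and an unadjusted p under 0.05). The first reading of this rule took every symbol ending in P and a number, such as MMP7, for a pseudogene. It was corrected to the annotated biotype after values were seen, which brought MMP7 into the 10 lower genes in place of TIMELESS. Symbols were matched to RefSeq on GRCh38 (14983 of 15458), which gave the coordinates. ARNTL is an older symbol with no match.

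The main fits, the gene lists, the naming rule and most alternatives were set before the data were examined. Alternatives changed the pairing (patient as a fixed block, as a random block with statmod 1.5.0, pairs without block, patients with 1 biopsy), the pseudocount (0.5, 10), the filter (none, mean of at least 50), the scaling (same total, same upper quartile, quantile, median log2 ratio), sample weights, eBayes settings, muscle and squamous scores as covariates, the threshold, and single libraries left out. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 were run on the recovered reads. Leaving out libraries under 5 M reads or the columns sharing a name, log2 reads as a covariate, the list tests in patients with 1 biopsy, and the list tests with the patient as a block and an estimated correlation were added after seeing the data. Counts of genes at an unadjusted p became a reported result after 0 adjusted calls were seen. Up to 100 other splits of the samples were drawn per result.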

Results

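Gene expression was measured by total RNA sequencing in 51 pinch biopsies of the rectum. The donors had ulcerative colitis, a chronic inflammation of the colon, and were treated with tofacitinib, an oral inhibitor of the Janus kinases (JAK) that pass cytokine signals on to STAT transcription factors. Week 0, before treatment, has 27 biopsies and week 24 has 24. The labels name 38 patients, 13 of them with a biopsy at each week, and 11 of these pairs could be matched to their values. The libraries held 1.44 to 36.6 M reads assigned to genes (M, mega), with a median of 8.59 M at week 0 (4.01 to 36.6 M) and 9.91 M at week 24 (1.44 to 17.2 M). The weeks did not differ detectably in log2 reads (difference −0.10, two-sided permutation p = 0.630) or in the share of reads from the signal recognition particle RNAs RN7SL1 and RN7SL2 (9.92% ± 9.74 at week 0 and 9.34% ± 7.54 at week 24, SD, permutation p = 0.817).

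The central question was how the rectal transcriptome after 24 weeks of treatment differs from that before it. No single gene passed limma's test across 15458 genes, and the 20 genes with the smallest p-values are given here with that limit. DESeq2, on recovered reads, called 13 of these 20, in a set of calls that moves with single libraries, and limma with a weight for each sample called 6 genes, all lower, among them MMP7, CXCL5, CHRDL2, ARNTL and MIAT. Among those lower at week 24, CXCL5 is on the cytokine list and MMP7 on the matrix list. MMP7, a secreted matrix metalloproteinase (chromosome 11, 102520508 to 102530747, GRCh38), had a mean normalized count of 93.6 ± 137 (SD, n = 27) at week 0 and 20.8 ± 30 (SD, n = 24) at week 24. Its log2 fold change was −2.33 ± 0.54 (SE). CXCL5, a chemokine that attracts neutrophils (chromosome 4, 73995642 to 73998677), went from a mean of 167 ± 171 to 73.3 ± 192, with a log2 fold change of −2.71 ± 0.70. CHRDL2, which encodes a chordin-like secreted protein, had a log2 fold change of −2.29 ± 0.54, and was lower at week 24 in 9 of the 11 pairs. The DNA helicase gene BLM had the smallest p of all (log2 fold change −0.69 ± 0.16, p = 4.47e-05, limma adjusted p = 0.237) and was lower in 7 of 11 pairs. The other 6 of the 10 lower genes were ARNTL, SUPT7L, MIAT, HELB, SNRPA1 and LINS1, with log2 fold changes between −0.98 and −0.33.

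Among the 10 higher genes, RXRA, the nuclear receptor for retinoids that pairs with several other receptors (chromosome 9, 134326455 to 134440585), had a mean of 1010.3 ± 167 (SD, n = 27) at week 0 and 1279 ± 255 (SD, n = 24) at week 24. That is a log2 fold change of 0.33 ± 0.08 (SE, p = 7.09e-05), with a higher value at week 24 in 9 of 11 pairs. KLK1, tissue kallikrein, which is also on the goblet cell list (chromosome 19, 50819146 to 50823787), had means of 109.9 ± 86.3 and 252 ± 244 and a log2 fold change of 1.27 ± 0.33. TEF, a transcription factor driven by the circadian clock (chromosome 22, 41367455 to 41399326), had means of 278 ± 186 and 502 ± 226 and a log2 fold change of 0.95 ± 0.23. GSN, which encodes the actin-severing protein gelsolin, had means of 4477 ± 1241 and 6084 ± 1662 and was higher in 9 of 11 pairs. CIB2, FAM13A, CST3, PKDCC, PSD3 and FCGRT complete the 10, with log2 fold changes of 0.37 to 0.78.

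**Figure D1:**
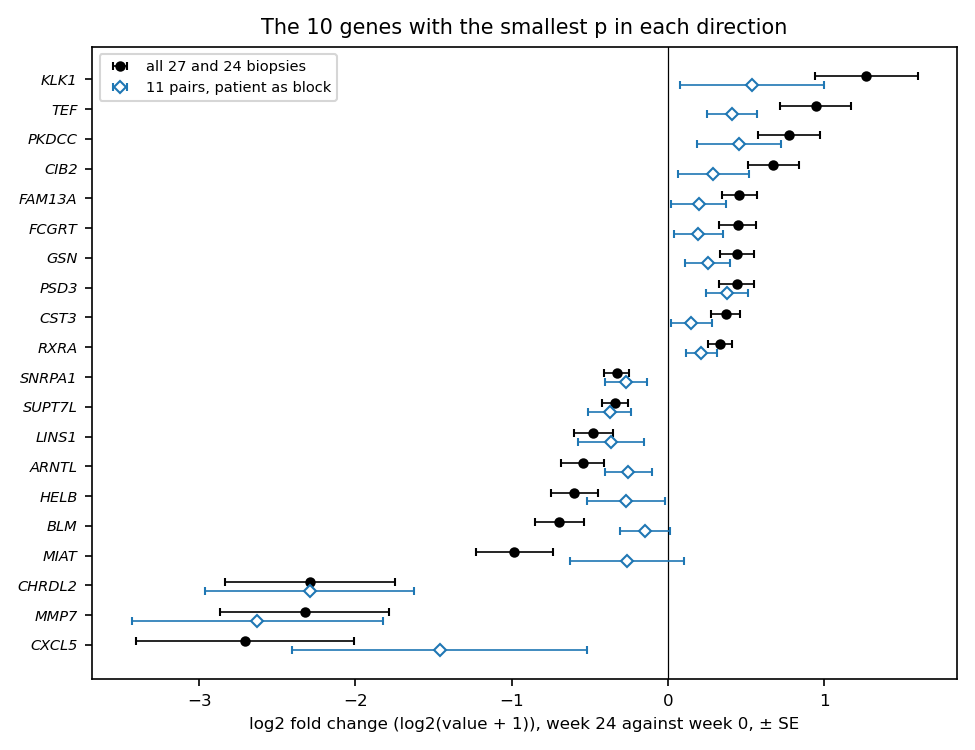
Log2 fold change, week 24 against week 0, on the log2(value + 1) scale, of the 10 genes with the smallest p in each direction. Filled circles are the fit of all 27 and 24 biopsies, open diamonds the fit of the 11 pairs with the patient as a block, and bars are ± 1 SE. None passes limma's adjusted threshold without sample weights, limma with them called 6 genes, DESeq2 called 13 of the 20, and CXCL5 has the lowest value (−2.71) and KLK1 the highest (1.27).

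In limma's main fit, 0 of 15458 genes passed an adjusted p of 0.05 (smallest adjusted p 0.237), against 1472 at an unadjusted p under 0.05 (636 higher, 836 lower). By chance 773 would be met on average, with a spread that correlated genes widen. On whole reads recovered from the same values, edgeR called 1 gene, APOB, and DESeq2 called 41, with 1518 and 1784 at an unadjusted p under 0.05. With 1 library left out at a time, the DESeq2 count ranged from 9 to 118. Within the 11 pairs, with the patient as a block, 256 genes reached an unadjusted p under 0.05, and in the patients with 1 biopsy 1614 did, with 0 adjusted calls by limma in either. By the labels, patients with only a week 24 biopsy mostly have lower patient numbers than those with only a week 0 biopsy. In these patients the week cannot be told apart from whatever the numbering follows, which the labels do not give. Across genes, which are not independent replicates, the fold changes of the pairs and those of the patients with 1 biopsy (14 at week 0, 11 at week 24) had r = 0.149 and the same sign for 52.3% of genes.

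Gene lists were then compared with all other genes, with counts of members from limma. Markers of neutrophils, the white cells that invade the mucosa in active colitis, were lower at week 24 in all 17 members tested, with a median log2 fold change of −1.18 (camera adjusted p = 9.46e-10, adjusted p = 0.319 with an estimated correlation). 10 members had an unadjusted p under 0.05, 8 passed when adjusted over the list alone, and 0 over all genes tested. S100A9, a subunit of calprotectin, had a mean of 566 ± 1110 (SD, n = 27) at week 0 and 179.5 ± 236 (SD, n = 24) at week 24, a log2 fold change of −1.72 ± 0.58 (SE). The formyl peptide receptors FPR1 and FPR2 had log2 fold changes of −1.51 ± 0.54 and −1.80 ± 0.59, and FPR1 was lower in 9 of 11 pairs. Inflammatory cytokines and chemokines were lower in 17 of 19 members (median −0.97, camera adjusted p = 9.72e-06, adjusted p = 0.319 with an estimated correlation). CXCL5, CXCL3 (−1.75 ± 0.49) and IL24 (−1.34 ± 0.44) are the 3 that passed when adjusted over the list alone, against 0 over all genes in the main fit, while limma with sample weights called CXCL5. The cytokine genes OSM (−0.63 ± 0.71) and IL11 (−0.84 ± 0.64), the decoy receptor gene IL13RA2 (−0.89 ± 0.51) and TREM1 (−1.56 ± 0.71), a receptor of myeloid cells, did not pass.

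Epithelial antimicrobial and stress genes were lower in 19 of 22 members (median −0.76, camera adjusted p = 0.000565, adjusted p = 0.515 with an estimated correlation). None passed over the list alone or over all genes. DUOXA2, the maturation factor of the hydrogen peroxide-making oxidase DUOX2, had a log2 fold change of −1.93 ± 0.68 and was lower in 9 of 11 pairs, and LCN2, which encodes the iron-withholding lipocalin of neutrophils and epithelium, had −1.31 ± 0.53. DEFA5, a defensin of Paneth cells, went the other way (1.96 ± 0.88). Matrix remodelling genes and markers of inflammatory fibroblasts were lower in 17 of 25 members (median −0.34, camera adjusted p = 0.00482, adjusted p = 0.642 with an estimated correlation and 0.400 in the pairs with the patient as a block). MMP7, CHI3L1 (−2.40 ± 0.72) and MMP3 (−1.94 ± 0.66, lower in 9 of 11 pairs) passed when adjusted over the list alone, and 0 over all genes tested in limma's main fit. DESeq2 and limma with sample weights called MMP7.

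The next lists are pathways downstream of the Janus kinases. Interferon-gamma response genes were lower in 21 of 21 members, with a median log2 fold change of −0.50 (camera adjusted p = 3.2e-11, adjusted p = 0.319 with an estimated correlation). Of these, 12 had an unadjusted p under 0.05 and 8 passed when adjusted over the list alone, against 0 over all genes. CXCL9, a chemokine for activated T cells, had a mean of 549 ± 501 (SD, n = 27) and then 305 ± 439 (SD, n = 24), a log2 fold change of −1.40 ± 0.48. GBP5, an interferon-induced GTPase, had −0.98 ± 0.31, and CIITA, the master regulator of MHC class II genes, −0.69 ± 0.22. The ligand gene IFNG itself had means of 13.6 ± 11.3 and 6.93 ± 7.13 (−0.98 ± 0.39), while the receptor genes IFNGR1 and IFNGR2 had log2 fold changes of 0.12 ± 0.15 and 0.12 ± 0.14. Type I interferon genes were lower in 19 of 22 members by a median of −0.24 (camera adjusted p = 0.00147, adjusted p = 0.515 with an estimated correlation and 0.488 with the patient as a block), and 0 passed over the list alone. MHC class II genes were divided, 5 higher and 5 lower (camera adjusted p = 0.996), and CIITA was the 1 that passed when adjusted over the list alone.

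JAK-STAT components were lower in 21 of 26 members, but by little (median −0.12, camera adjusted p = 0.000964, adjusted p = 0.319 with an estimated correlation and 0.369 with the patient as a block). JAK3, the kinase of the common gamma chain receptors, had a log2 fold change of −0.65 ± 0.25, JAK2 −0.26 ± 0.12, TYK2 −0.20 ± 0.11 and JAK1 −0.09 ± 0.07. STAT4 (−0.56 ± 0.20), STAT5A (−0.32 ± 0.12), SOCS1 (−0.54 ± 0.26), SOCS3 (−0.94 ± 0.42) and the phosphatase gene PTPN2 (−0.25 ± 0.08) were, with JAK2 and JAK3, among the 8 with an unadjusted p under 0.05. STAT2, STAT3, STAT5B, STAT6, CISH, SOCS2, SOCS4, SOCS5, SOCS6, SOCS7, PTPN6, PTPN11 and the 4 PIAS genes lay between −0.25 and 0.17. STAT3 and IL-6 family genes were lower in 18 of 21 members (median −0.28, camera adjusted p = 0.000826, adjusted p = 0.406 with an estimated correlation), and SERPINA3 (−1.70 ± 0.50), an acute phase protein, was the 1 to pass over the list alone. STAT5 and common gamma chain genes were lower in 15 of 17 (median −0.32, camera adjusted p = 0.000709, adjusted p = 0.319 with an estimated correlation and 0.551 with the patient as a block), with IL2RA at −1.05 ± 0.39 and IL15RA at −0.55 ± 0.18. None of these components and family members passed over all genes tested in limma.

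Lymphocyte lists were lower as sets in the whole series. Against other genes, camera placed 3 of them the other way within the pairs, where the same patient had the largest rise in each. Cytotoxic lymphocyte genes were lower in 14 of 16 members (median −0.66, camera adjusted p = 8.8e-06, adjusted p = 0.319 with an estimated correlation). TBX21, the transcription factor of type 1 immunity (−1.24 ± 0.34), and GZMH, a granzyme (−1.36 ± 0.46, lower in 10 of 11 pairs), passed when adjusted over the list alone. Regulatory T cell and costimulation genes were lower in 13 of 13 (median −0.45, camera adjusted p = 7.65e-05, adjusted p = 0.319 with an estimated correlation and 0.565 with the patient as a block), with LAG3, an inhibitory receptor (−0.84 ± 0.26), the 1 that passed over the list alone. T cell genes were lower in 14 of 15 members in the whole series (median −0.48, camera adjusted p = 4.12e-05, adjusted p = 0.406 with an estimated correlation). Within the pairs, 12 of the 15 were higher (median 0.22, camera adjusted p = 0.212 with the patient as a block). The T cell score, the mean over these genes, was nonetheless lower in 7 of 11 pairs, and in 1 patient it rose from −2.43 to 0.90. B cell and follicle genes were lower in 16 of 18 (median −0.46, camera adjusted p = 0.00566, adjusted p = 0.642 with an estimated correlation), and plasma cell genes in 8 of 10 (median −0.49, camera adjusted p = 0.0177, adjusted p = 0.532 with an estimated correlation). The plasma cell list had 19 members, of which only these 10 could be tested. Against other genes both sets pointed upward in the pairs with the patient as a block (camera adjusted p = 0.488 and 0.383), though 6 of the 10 plasma cell genes were lower there (median −0.0065). Each of the 2 scores was higher in 6 of 11 pairs. In the patient with the large T cell rise, they went from −2.07 to 1.05 and from −1.31 to 0.74. Without this patient the mean changes of the T cell, B cell and plasma cell scores were negative. No T cell, B cell or plasma cell gene passed over its list alone, and no lymphocyte gene passed over all genes tested in limma.

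Markers of mature epithelium were higher in the whole series. Surface colonocyte genes were higher at week 24 in 23 of 24 members, with a mean log2 fold change of 1.10 (camera adjusted p = 3.2e-11, adjusted p = 0.319 with an estimated correlation and 0.488 with the patient as a block). GUCA2B, the hormone uroguanylin, had a mean of 148 ± 237 (SD, n = 27) at week 0 and 329 ± 369.8 (SD, n = 24) at week 24 (log2 fold change 2.01 ± 0.68). PADI2 (1.32 ± 0.44) and the transporter gene ABCG2 (1.07 ± 0.37) were the other 2 of the 3 that passed when adjusted over the list alone, of 11 with an unadjusted p under 0.05. Goblet cell genes, of the cells that make mucus, were higher in 18 of 19 members (median 0.71, camera adjusted p = 1.84e-09, adjusted p = 0.319 with an estimated correlation and 0.551 with the patient as a block). KLK1, ZG16, a lectin-like protein of the mucus (778 ± 875 and 2492 ± 2944, log2 fold change 2.20 ± 0.61), and SPDEF, the transcription factor of goblet cell maturation (0.71 ± 0.25), passed over the list alone. Mitochondrial fatty acid oxidation genes were higher in 21 of 22 (median 0.19, camera adjusted p = 4.28e-06, adjusted p = 0.379 with an estimated correlation and 0.438 with the patient as a block), led by ACADS (0.61 ± 0.21), the dehydrogenase of short-chain fatty acids. In the pairs, however, 13 of these 22 were lower (median −0.0172), as were 10 of 19 goblet cell genes (median −0.0271). Surface colonocyte genes were higher there in 15 of 24 (median 0.12). Enteroendocrine genes were higher in 10 of 13 (median 0.28, camera adjusted p = 0.00667, adjusted p = 0.515 with an estimated correlation), and the peptide hormone genes SST (1.19 ± 0.58) and INSL5 (1.30 ± 0.54) were among the 4 with an unadjusted p under 0.05. SST was higher in 10 of 11 pairs. In these 4 lists 0 genes passed over all genes tested in limma, while DESeq2 called KLK1. Crypt base and stem cell genes did not pass (12 of 14 higher, median 0.11, camera adjusted p = 0.199), nor did tight junction genes (15 of 20 higher, median 0.21, camera adjusted p = 0.0692). Within the pairs, crypt base and stem cell genes were instead lower in 10 of 14 (median −0.07, camera adjusted p = 0.565 with the patient as a block). Tight junction genes were lower there in 17 of 20 (median −0.33, camera adjusted p = 0.00197 with the patient as a block, adjusted p = 0.904 with the block and an estimated correlation).

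Proliferation genes were lower in 23 of 23 members, by a median of −0.41 (camera adjusted p = 9.46e-10, adjusted p = 0.319 with an estimated correlation and 0.176 with the patient as a block). BUB1, a mitotic checkpoint kinase, had a log2 fold change of −0.76 ± 0.25. CCNB1, cyclin B1, had means of 193 ± 95.5 (SD, n = 27) and 137 ± 86.3 (SD, n = 24), a log2 fold change of −0.65 ± 0.23, and 0 of the 9 with an unadjusted p under 0.05 passed over the list alone. Replication-dependent histone genes, whose copies are near-identical and whose values are therefore uncertain, were lower in 13 of 14 (median −0.21, camera adjusted p = 0.0177, adjusted p = 0.642 with an estimated correlation and 0.826 with the patient as a block). In the pairs 8 of the 14 were lower (median −0.0117), which placed the set just above other genes. Endothelial and adhesion genes were lower in 17 of 19 (median −0.27, camera adjusted p = 0.0253, adjusted p = 0.708 with an estimated correlation and 0.176 with the patient as a block), with the leukocyte adhesion genes SELE at −1.53 ± 0.67 and SELP at −0.85 ± 0.37.

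Of the other lists, monocyte and macrophage genes were lower in 12 of 19 members (median −0.04, camera adjusted p = 0.0692), with FCGR3A at −1.33 ± 0.46 and SPP1 at −1.18 ± 0.39. Th17 and type 3 cytokine genes were divided, 5 lower and 4 higher (camera adjusted p = 0.917), with IL17A at −1.07 ± 0.50. Cholesterol synthesis genes (camera adjusted p = 0.134), immediate early and heat shock genes (0.373), squamous epithelium (0.669), mast cells (0.996), smooth muscle (0.151), enteric glia and neurons (0.669) and red blood cells (0.370) did not pass either, and FDPS (−0.41 ± 0.13), of cholesterol synthesis, was the 1 of their members that passed over the list alone. In the pairs with the patient as a block, cholesterol synthesis (camera adjusted p = 0.000672), immediate early and heat shock (0.000239) and squamous epithelium (0.0199) did pass, all lower, though not with the block and an estimated correlation (adjusted p = 0.904 for each). The mean, the median and the test differed in sign for MHC class II (mean 0.11, median −0.00, set higher), red blood cells (0.40, −0.03, set higher), enteric glia and neurons (−0.00, 0.13, set higher) and mast cells (−0.01, −0.11, set higher).

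**Figure D2:**
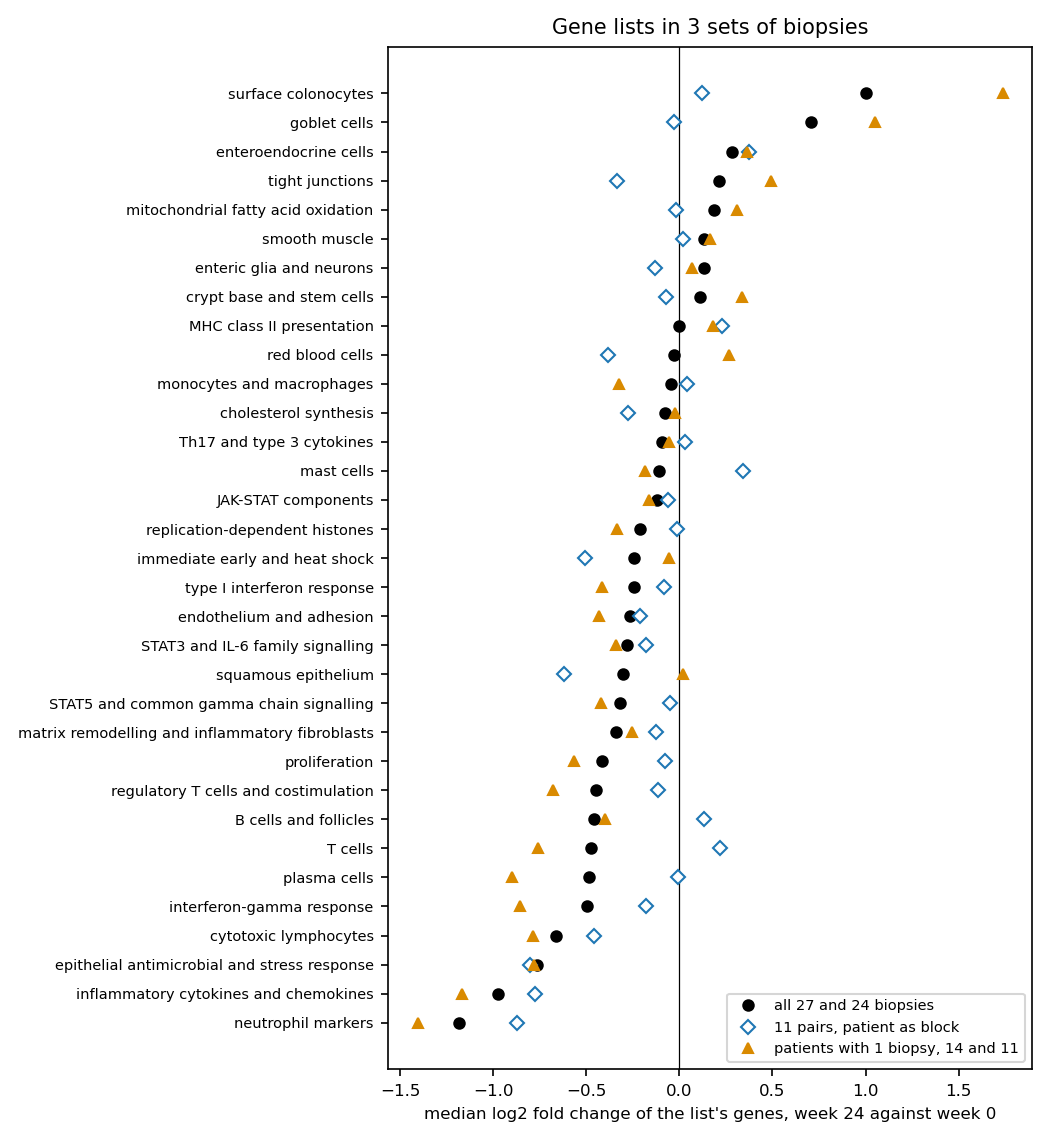
Median log2 fold change of the genes of each of 33 lists, week 24 against week 0. Filled circles are all 27 and 24 biopsies, open diamonds the 11 pairs with the patient as a block, and triangles the patients with 1 biopsy (14 and 11). Neutrophil markers are lowest in all biopsies (−1.18; −0.87 in the pairs), and surface colonocytes are highest in all biopsies but near 0 in the pairs (0.12).

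With camera's preset correlation 17 of 33 lists were lower and 4 higher, and with an estimated correlation 0 of the 21 calls held (smallest adjusted p 0.319). In the pairs with the patient as a block 11 lists passed (10 lower, 1 higher), 7 of them among the 21 and in the same direction, and 0 of the 11 with an estimated correlation.

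Each biopsy was also given a score per list, the mean of its centred log2 values. The neutrophil score averaged 0.59 ± 1.98 (SD, n = 27) at week 0 and −0.66 ± 1.82 (SD, n = 24) at week 24, a difference of −1.25 (permutation p = 0.0221, adjusted p = 0.135). Biopsies of the same week thus differed from each other by more than the weeks did. The surface colonocyte score averaged −0.52 ± 1.94 and 0.58 ± 1.65 (difference 1.10, permutation p = 0.0359, adjusted p = 0.135). The interferon-gamma score went from 0.32 ± 0.83 to −0.36 ± 1.01 (difference −0.69, permutation p = 0.0104, adjusted p = 0.135), the cytotoxic lymphocyte score differed by −0.64 (permutation p = 0.0130), and the goblet cell score by 0.72 (permutation p = 0.0300). Of 33 lists, 11 had an unadjusted permutation p under 0.05 and 0 an adjusted one.

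**Figure D3:**
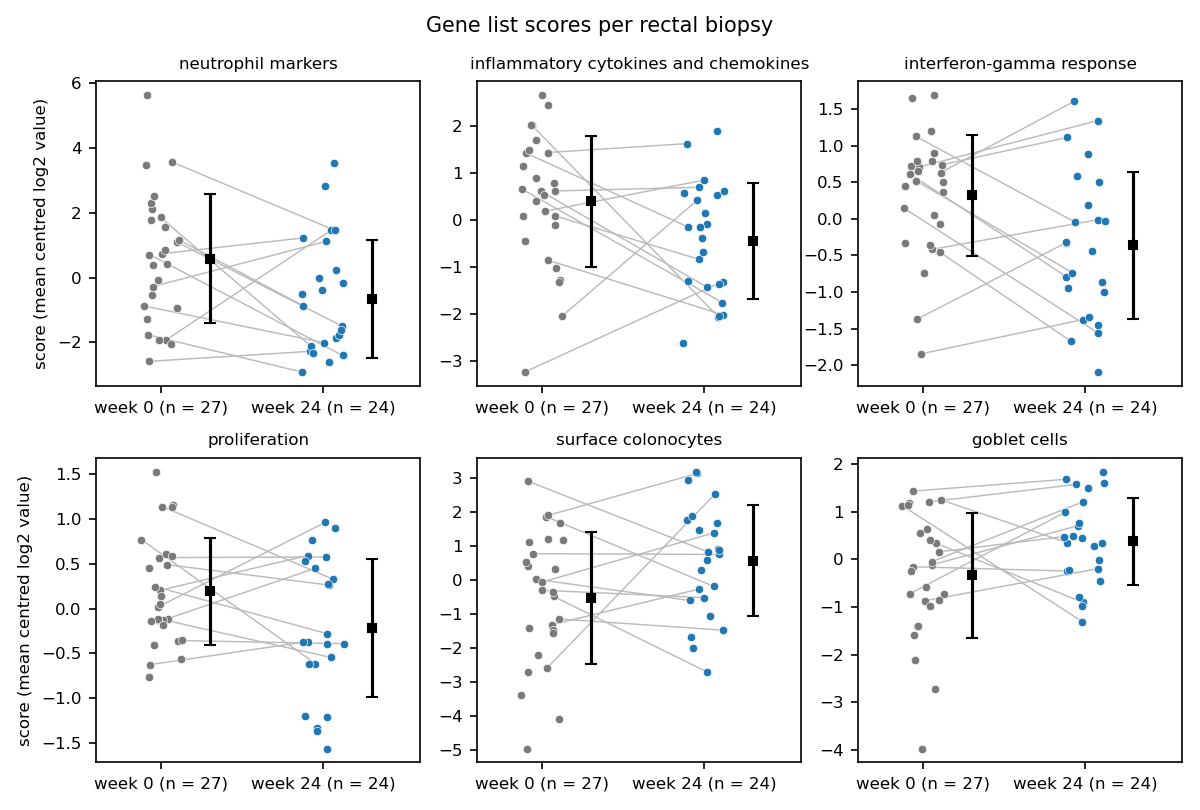
Scores of 6 gene lists in each biopsy, as the mean of centred log2(value + 1), at week 0 (n = 27) and week 24 (n = 24). Points are biopsies, thin lines join the 11 pairs, and squares with bars are the mean ± SD. The weeks overlap widely in every panel, with neutrophil means of 0.59 and −0.66.

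Within the 11 pairs, the neutrophil score was lower at week 24 in 7 patients (mean change −0.96 ± 2.17, SD, exact sign-flip p = 0.173). Surface colonocytes had a mean change of 0.12 ± 2.12 (exact sign-flip p = 0.878) and were lower in 7 pairs and higher in 4. The interferon-gamma score was lower in 5 pairs and higher in 6 (mean change −0.26 ± 1.08, exact sign-flip p = 0.431). 0 of 33 lists had an unadjusted or adjusted p under 0.05 (smallest adjusted p 0.931).

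Whether a patient's level at week 0 carried over to week 24 was asked across the same 11 patients. The neutrophil score at the 2 weeks had r = 0.273 (permutation p = 0.415) and rho = 0.255 (p = 0.451), and r = −0.161 without the 2 patients farthest from the median. For MHC class II presentation r was 0.576 (permutation p = 0.0657) and rho 0.591 (p = 0.0620), and r was 0.471 without the 2 farthest. 0 of 33 lists passed, adjusted or not (smallest adjusted p 0.705). The spread between biopsies was wider at week 24 for MHC class II (SD 0.79 and 1.24, permutation p = 0.0240, adjusted p = 0.791), the 1 list of 33 with an unadjusted p under 0.05, and 0 passed after adjustment.

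Within each week, 3 list scores were set against the neutrophil score. The surface colonocyte score was lower where the neutrophil score was higher, at week 0 (r = −0.700, rho = −0.754, n = 27, permutation p = 3e-05 and 2e-05, adjusted p = 0.00018 and 0.00012) and at week 24 (r = −0.406, rho = −0.465, n = 24, permutation p = 0.0494 and 0.0231, adjusted p = 0.0494 and 0.0231). The week 24 r does not pass with the median over members as the score (adjusted p = 0.0557), and among 64 relations of the neutrophil score the rho passes (adjusted p = 0.0493) and the r does not (adjusted p = 0.093). The interferon-gamma score was higher with it at week 0 (r = 0.657, rho = 0.654, permutation p = 0.00022 and 0.00033, adjusted p = 0.00044 and 0.00066) and at week 24 (r = 0.698, rho = 0.760, permutation p = 0.00019 and 6e-05, adjusted p = 0.00044 and 0.00018). So was the plasma cell score at week 0 (r = 0.552, rho = 0.559, permutation p = 0.00306 and 0.00303, adjusted p = 0.00459 and 0.00364) and at week 24 (r = 0.542, rho = 0.604, permutation p = 0.00638 and 0.00203, adjusted p = 0.00766 and 0.00305). Adjustment was over these 6 relations. Without the 2 biopsies farthest from the median neutrophil score, r was −0.642, 0.649 and 0.526 at week 0 and −0.404, 0.850 and 0.712 at week 24.

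**Figure D4:**
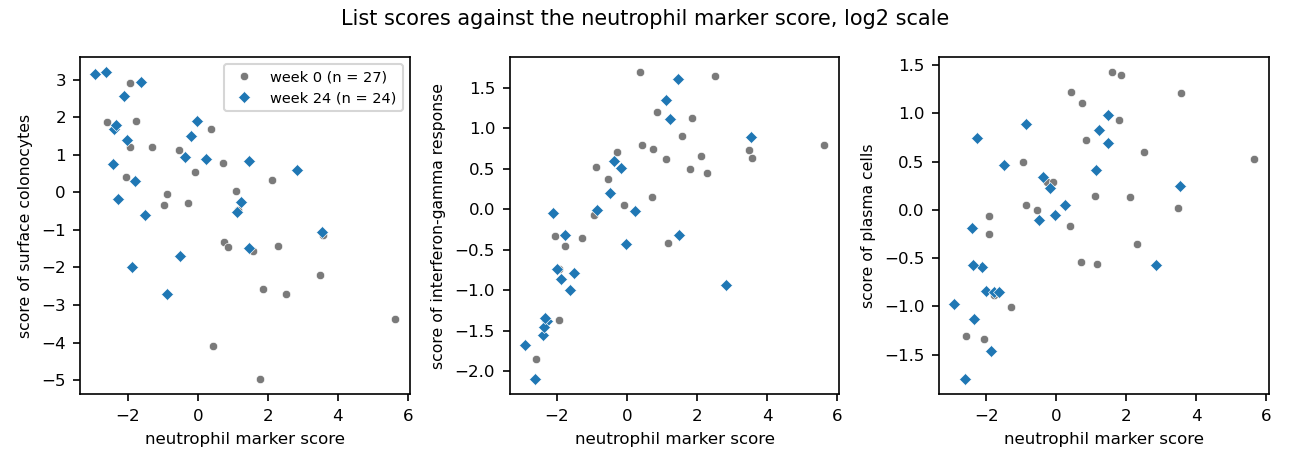
Scores of surface colonocytes, interferon-gamma response and plasma cells against the neutrophil marker score of the same biopsy, all as means of centred log2 values. Circles are week 0 (n = 27) and diamonds week 24 (n = 24). The colonocyte score goes down as the neutrophil score goes up (r = −0.700 and −0.406, the second not passing with the median over members), and the other scores go up.

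The patients sampled at the 2 weeks overlap only in part, so patients with both biopsies were compared with patients with 1. At week 0 (13 and 14 biopsies), at week 24 (11 and 11) and in the difference of the change (24 and 25 biopsies), limma called 0 genes each, with 1300, 351 and 523 at an unadjusted p under 0.05 (no other tool was run on these). Among the scores, the surface colonocyte change was 0.12 in patients with both biopsies and 1.92 in patients with 1 (difference −1.80, permutation p = 0.0844, adjusted p = 0.772), and the neutrophil change −0.85 and −1.57 (difference 0.72, permutation p = 0.527, adjusted p = 0.791). These permutations reassigned the status within each week and did not keep pairs together. The colonocyte change of 0.12 also leans on 1 patient, whose score rose from −2.58 to 2.55. 0 of 33 lists differed in their change, adjusted or not.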

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

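Chosen only after the result was seen were the tests without libraries under 5 M reads, without the columns sharing a name, with log2 reads as a covariate, the list tests in patients with 1 biopsy, and those with the patient block and an estimated correlation. The count of genes at an adjusted p under 0.05 was 0 in limma in every alternative run but sample weights, which called 6, all lower, and edgeR called 1 and DESeq2 41 on recovered reads. The cause was not tested beyond single libraries. With 1 library left out at a time limma called 0 to 0 genes, and 1285 to 1870 at an unadjusted p under 0.05 (smallest adjusted p 0.102 to 0.386). The unadjusted count of 1472 was 256 with the replicate block, 148 in the 11 pairs without it and 233 in edgeR with the block, 1614 in patients with 1 biopsy, who are fewer samples too, and between 1187 and 2122 in the others. The cause was not tested. Rescaling to the same total moved its split from 636 higher and 836 lower to 333 and 1083 (43.2% and 23.5% higher).

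The 21 list calls were 0 with an estimated correlation, 0 with fry, 11 with the replicate block, 0 with the block and an estimated correlation, and 20 to 24 otherwise. Under the block camera's direction, which is relative to all other genes, was the other way for some lists. These were tight junctions (camera adjusted p = 0.00197), T cells (0.212), B cells (0.488), plasma cells (0.383) and histones (0.826). Crypt base and stem cells (0.565), enteric glia and neurons (0.705) and red blood cells (0.538), which passed in neither fit, also went from higher to lower. With an estimated correlation the adjusted p was 0.904 for each of T cells, B cells and plasma cells and 0.955 for histones. Plasma cell and histone genes were still lower there in 6 of 10 and 8 of 14 members (medians −0.0065 and −0.0117). For T cells, B cells and plasma cells the upward mean score change in the pairs rested on 1 patient. The cause was not tested, and different patients enter these fits. The block changed no other call than those printed. 1 list, MHC class II, passed for spread with the median over members (adjusted p = 0.0119), where its main value was 0 lists, and the cause was not tested. With that median 5 of 6 relations passed (surface colonocytes at week 24, adjusted p = 0.0557). Comparisons of patients with both biopsies and with 1 kept 0 calls under each alternative run. Depth limits genes near the filter: at a mean of 10 or more 15458 genes were tested, and at 50 or more 12159.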

Other observations

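Chosen only after the result was seen were the tests of the neutrophil score against all other lists, the clock gene scores and their tests, the tests of the epithelial share, of different patients and of colon identity, and the splits of counts at an unadjusted p and of the DESeq2 calls. The depth test was rewritten once, after a first version on gene counts.

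Some immune lists went with the neutrophil score in both weeks, and others, such as T cells, B cells, mast cells and Th17 genes, passed in neither. Of 64 relations of the neutrophil score with the 32 other lists in the 2 weeks, judged by r, 12 were positive and 3 negative at an adjusted p under 0.05 at week 0, 13 and 2 at week 24, and 10 lists were positive and 0 negative in both. Surface colonocytes at week 24, past the threshold in the family of 6, passed in this one by rho (adjusted p = 0.0493) but not by r (adjusted p = 0.093). Inflammatory cytokines and chemokines, which share TREM1 with the neutrophil list, followed it most closely (week 0 r = 0.905, rho = 0.953, r without the 2 farthest 0.914; week 24 r = 0.880, rho = 0.889, r without the 2 farthest 0.881). Their permutation p of 1e-05 is the smallest that can be had (adjusted p = 0.00016). Monocyte and macrophage genes had r = 0.717 and rho = 0.660 at week 0 (adjusted p = 0.000256 and 0.00139, r without the 2 farthest 0.650) and r = 0.746 and rho = 0.815 at week 24 (adjusted p = 0.00032 and 0.00016, r without them 0.724). MHC class II genes had r = 0.131 and rho = 0.165 at week 0 (adjusted p = 0.596 and 0.468, r without them 0.259) and r = 0.613 and rho = 0.671 at week 24 (adjusted p = 0.00505 and 0.00196, r without them 0.572), a difference that was not tested. Mitochondrial fatty acid oxidation was opposed at week 0 (r = −0.656, rho = −0.647, adjusted p = 0.00101 and 0.00151, r without them −0.606) and crypt base and stem cell genes at week 24 (r = −0.662, rho = −0.585, adjusted p = 0.00228 and 0.00808, r without them −0.488).

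The first pattern weighed is the lower neutrophil and higher surface colonocyte score at week 24. Depth is argued against, since the part of the difference that goes with log2 reads was 0.06 (0.0647, 95% bootstrap interval −0.190 to 0.478) of −1.25 for neutrophils and −0.04 (−0.0402, −0.246 to 0.168) of 1.10 for colonocytes. A larger share of epithelium in the biopsies, which would lower all other cell types alike, stays open: the neutrophil score fell against the mean of the smooth muscle and enteric glia scores by −1.32 (permutation p = 0.0418, not adjusted and for a list picked as the lowest), but in the pairs by −0.96 ± 2.66 (SD, exact sign-flip p = 0.253). Different patients at the 2 weeks stay open too, as a possible explanation of the colonocyte difference, as its change was 0.12 in patients with both biopsies and 1.92 in the others (permutation p = 0.0844, pairs not kept together), with an exact sign-flip p of 0.878 in the pairs. In the patients with 1 biopsy the week also went with the patient number, as said above. An effect of treatment stays open and was not tested, since every week 24 biopsy is also the later one.

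The second pattern was noticed in the values: TEF, among the highest genes, and ARNTL, among the lowest, belong to opposite phases of the circadian clock. Of 19 clock genes then looked at, 8 had an unadjusted limma p under 0.05 (7 higher, 1 lower) and 0 an adjusted one, and 13 chosen after their values were seen went into the scores, and the others were left out. The score of the 9 output genes (among them PER3, log2 fold change 0.91, HLF, 1.09, and NR1D2, 0.57) minus that of 4 genes of the opposite phase was higher at week 24 by 0.90 (permutation p = 0.00106), and in the pairs by 0.50 ± 0.66 (SD, higher in 7 of 11, exact sign-flip p = 0.0293). Without TEF and ARNTL the difference was 0.76 (permutation p = 0.00537; exact sign-flip p = 0.0752 in the pairs). Most of the 0.90 came from the output genes, whose score was higher by 0.69, while the opposite phase score was lower by 0.21. Of its 4 genes ARNTL had a log2 fold change of −0.55, against −0.08 for CLOCK, −0.04 for NPAS2 and −0.19 for NFIL3 (unadjusted limma p = 0.272, 0.801 and 0.331). Each of the 4 was lower in 8 of 11 pairs. These p-values come from genes picked on the same data and do not measure evidence.

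The part of the clock difference that goes with the surface colonocyte score was 0.04 (0.0351, 95% bootstrap interval −0.124 to 0.230) of 0.90. That argues against this score as the main source of the 0.90, but the 0.90 comes from genes picked on these values, and in the pairs the difference was 0.50. The r with that score is uncertain too: 0.178 at week 0 (rho = 0.098, permutation p = 0.375, upper 95% limit 0.523) and −0.061 at week 24 (rho = −0.062, permutation p = 0.779, upper 95% limit 0.351), or 0.315 and 0.064 without the 2 farthest. A larger share of mature epithelium that this score does not capture is therefore not excluded. Less inflammation may contribute and stays open, as the part that goes with the neutrophil score was 0.23 (95% bootstrap interval 0.0292 to 0.488), and r with the neutrophil score was −0.389 at week 0 (rho = −0.277, permutation p = 0.0461, adjusted p = 0.0921) and −0.382 at week 24 (rho = −0.275, permutation p = 0.0649, adjusted p = 0.0973), or −0.208 and −0.279 without the 2 farthest. Biopsies taken at different times of day cannot be told apart from it, because the labels give no time: output and opposite phase scores were opposed within both weeks (r = −0.566, rho = −0.444, adjusted p = 0.0110 and 0.0646 at week 0; r = −0.519, rho = −0.505, adjusted p = 0.0289 and 0.0646 at week 24; −0.390 and −0.558 without the 2 farthest), as a running clock would make them.

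The third pattern is the 41 genes that DESeq2 called on the recovered reads, 32 higher and 9 lower, where limma called 0 and edgeR 1. APOB, the apolipoprotein of intestinal lipid export, leads them, with means of 5.02 ± 9.83 and 95.2 ± 294, and 84.3% of its week 24 sum lies in 3 libraries, as does a median of 36.8% for the genes called higher and 21.5% for all genes. Single libraries fit as a source of the number: with each of the 51 left out in turn it ranged from 9 to 118, both without a week 24 library, with 6 libraries (4 of week 24) lowering and 8 (5 of week 24) raising it by over 1.5 times. Tissue of the ileum in some biopsies stays open: it needs a negative r of APOB with 3 colon identity genes at week 24, and the r of 0.145 (rho = 0.120, permutation p = 0.499; −0.0802 without the 2 farthest) is too uncertain to decide. Of 40 splits first drawn, the real one included, 2 called as many genes, and when the number was raised to 100 after that result was seen, 3 did (highest other 983, several times the real number, which points to a structure of the samples that was not tested), so chance cannot be called excluded.

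Other splits of the biopsies, parting the same 11 pairs, were drawn 100 times with the real one included. For the 0 genes at an adjusted p the count decides nothing, since every split gives at least 0 (100 of 100, highest other 0). The 1472 genes at an unadjusted p were reached by 10 of 100 (highest other 3507), and the 21 lists by 6 of 100 (highest other 23), so chance is excluded for neither. With no regard to pairs, 17 and 9 of 100 reached them. Among patients with and without the other biopsy, 18 of 100 splits reached the 1300 genes of week 0 (highest other 3570), 57 the 351 of week 24 (highest other 4801) and 53 the 523 of the difference of the change (highest other 3292), and chance is excluded for none. The counts of 4801 and 3292 are several times the real ones, which points to a structure of the samples that was not tested here.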
